A study of Mus musculus with 20 samples.

How the data were processed

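Single cells from mouse bone marrow (strain C57BL/6J) were sorted by surface markers and sequenced with Quartz-Seq, a method that copies the polyadenylated RNA of 1 cell and amplifies it by PCR. Each of the 20 samples was 1 cell. By the labels, 11 cells had been sorted as lineage-negative, cKit-positive and CD150-negative (here CD150- cells), and 9 as lineage-negative, cKit-positive, CD150-positive and CD48-negative (here CD150+CD48- cells). Every cell was lysed in a buffer with a diluted mix of ERCC spike-in RNA, per the labels' protocols, so that reads of the spike-ins give a yardstick for the amount of mRNA per cell. The titles carry codes with the letters A and B for CD150+CD48- cells and C and D for CD150- cells, and these codes name the cells below. What the letters stand for is not given in the sources used here. Each letter occurs in 1 group only, so anything they mark and the sort cannot be told apart.

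The deposited values were whole-number counts of reads per gene, with no normalization. The submitters' processing notes name HTSeq, R 3.0.2 and the genome build GRCm38, and the aligner and the annotation release are not given in the sources used here. Quartz-Seq as used here had no molecular identifiers, so a read is a PCR copy and not a molecule. Each cell's file held 38561 Ensembl genes and 5 summary rows of HTSeq. A table of the whole series held 18464 of these genes, with counts equal to those of the single files, and 51 ERCC rows. The summary rows and the ERCC rows were kept out of library sizes and levels. Of all reads in a cell's file, 2.49% to 80.2% were unaligned and 9.41% to 56.4% aligned to more than 1 place, so that 7.96% to 44.3% were counted in genes. Reads with several alignments were in a row of their own, so genes with near-identical copies, such as haemoglobin genes, Gapdh, ribosomal protein genes and some mitochondrial genes, were undercounted to an unknown degree. Class I genes of the MHC have close paralogs too.

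Gene reads per cell ranged from 660007 to 5776125. No cell was under the minimum of 200000 gene reads, and all 20 were used. Each cell was thinned without replacement to 660007 gene reads, the lowest total, and the thinned reads of a group's cells were summed and given as CPM, read counts scaled by the total of gene reads. At this depth 1 read in a cell is 1.52 CPM. Genes with at least 10 thinned reads over all cells and a read in at least 3 cells were kept, 11341 in all. Gene symbols were matched for 36639 of the 38561 identifiers. Reads of PCR copies are not independent molecules. Log2 folds are CD150+CD48- over CD150- with a pseudocount of 1 CPM, which understates differences of low genes. The labels name no animal or culture and cells are not replicates, so each group counted as 1 sample. No test between the groups was made, and no p-value, standard error or count of changed genes is given. Levels carry exact Poisson intervals, folds exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95%. They cover counting error only, of reads for levels and folds and of cells out of 9 or 11 for shares. Those of levels and folds leave out the differences between cells, and all leave out those between animals. Where a group had 0 reads, the fold is a bound with a floor of 3 reads over the group, which is 0.505 CPM for the CD150+CD48- cells and 0.413 CPM for the CD150- cells.

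Before the data were examined, 22 gene lists, the rule for named genes and the alternatives were fixed, with the exceptions given below. Of these, 16 had at least 3 members past the gene filter. The median log2 fold of each was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean expression, and a list is said to stand apart where its median lay outside the 2.5 to 97.5 percentile range. The percentile describes these libraries and is not a p-value. One listed erythroid symbol, Ahsp, matched no identifier. Cdkn1c is a member of both the HSC list and the list of G1 cyclins and CDK inhibitors. Cd9 and Irf7 were taken by the share of cells and are also members of the megakaryocyte and interferon lists. Named genes are the gate genes Slamf1, Cd48 and Kit, in each direction the 12 genes with the largest difference in share of cells with a read, and up to 4 members of each list, those with the 2 highest and the 2 lowest log2 folds. A gene of the second kind needed a read in at least 50% of cells of the higher group and a log2 fold of at least 1 in size that kept its direction whichever cell was left out. Ties went to the larger log2 fold, and predicted genes were passed over. Some other list members are named as examples and were chosen after their values were seen. The values of 1 gene are not reported here. Coordinates are from GENCODE M21, on GRCm38.

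The steps were tested on simulated counts with the totals, mean levels and spread of the 20 cells. Of 100 genes raised 4-fold in the CD150+CD48- cells, 90 had the right direction, with a median log2 fold of 1.80. Of 100 genes lowered 8-fold, 99 had the right direction, with a median of -2.89. Both sets were drawn from genes with a mean over 20 CPM, so these shares do not cover lower genes, among them several named below. Of 100 unchanged lists of 20 genes, 6 stood apart. The simulated genes varied independently of each other. This rate therefore does not cover lists whose members rise together in the same cells. Sorted cells were 1 per sample and no doublet caller was run.

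Alternatives were reads without thinning, the mean of each cell's CPM, the mean on the log scale, TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), scaling to the ERCC reads, pseudocounts of 0.1 and 10 CPM, other gene filters, a threshold of 5 reads for detection, another seed, a lower depth, leaving out each cell in turn, and subsets by letter. Alternatives were placed among 2000 random lists. Leaving out cells with over 40% unaligned reads, and replacing 0 reads by the floor with no pseudocount, were chosen after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.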

Results

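The data are gene expression profiles of 20 single mouse bone marrow cells of the lineage-negative, cKit-positive compartment, which holds blood stem and progenitor cells. CD150, the product of Slamf1, and CD48 are surface proteins used to enrich stem cells, which are mostly CD150-positive and CD48-negative. The comparison asked how 9 CD150+CD48- cells differed from 11 CD150- cells, the latter with no CD48 gate in their label. Gene reads ranged from 660007 to 3722713 in CD150+CD48- cells and from 996440 to 5776125 in CD150- cells. With no animal or culture named there was 1 sample per group, so differences have no replicate error.

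Genes of blood stem cells and of megakaryocytes were higher in CD150+CD48- cells, and genes of red cell precursors and of G2/M phase were lower. Of the 22 stem cell (HSC) genes past the filter, 19 were higher, with a median log2 fold of 1.62, and of the 15 megakaryocyte and platelet genes 12 were higher, with a median of 2.60. All 18 erythroid genes and 24 of 25 G2/M genes were lower, with medians of -4.68 and -4.60. None of 10000 random lists of matched expression had a median as far out as any of these 4 lists. The erythroid and G2/M reads of CD150- cells were concentrated in 7 of the 11 cells, and their HSC reads in the other 4, whose shares of the HSC list lay in the range of CD150+CD48- cells.

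Among the gate genes, Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, GRCm38) had reads in all 20 cells, at 620 CPM (95% CI 600 to 640) in CD150+CD48- cells and 374 CPM (95% CI 360 to 389) in CD150- cells. Slamf1 (ENSMUSG00000015316, chromosome 1, 171767127 to 171801184) had reads in 3 of 9 CD150+CD48- cells (33.3%, 95% CI 7.49 to 70.1), with 353 in B12, 28 in B11 and 1 in A8. It had none in the 11 CD150- cells, which allows a share of up to 28.5%. Cd48 (ENSMUSG00000015355, chromosome 1, 171682009 to 171705258) had 489 reads in B3, a cell sorted as CD48-negative, and none in the other 19 cells. As genes of the gate these are no finding.

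By the group medians CD150+CD48- cells also had fewer genes detected and fewer gene reads relative to the spike-ins. The median of gene reads per ERCC read was 68.1 (range 22.3 to 109) against 141 (range 12.7 to 302) in CD150- cells. The latter were of 2 kinds, with 109 to 302 in the 7 cells rich in erythroid reads, and 12.7, 24.3, 36.1 and 43.8 in D3, D11, D9 and D12, all below the CD150+CD48- median. At equal depth the median number of genes with a read was 5374 (range 4758 to 8693) against 8350 (range 5435 to 8877). The median share of unaligned reads was 29.8% against 8.55%. Over all genes past the filter the share of cells with a read was on average -10.7 percentage points apart (CD150+CD48- minus CD150-), which is the background for share differences below.

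**Figure D1:**
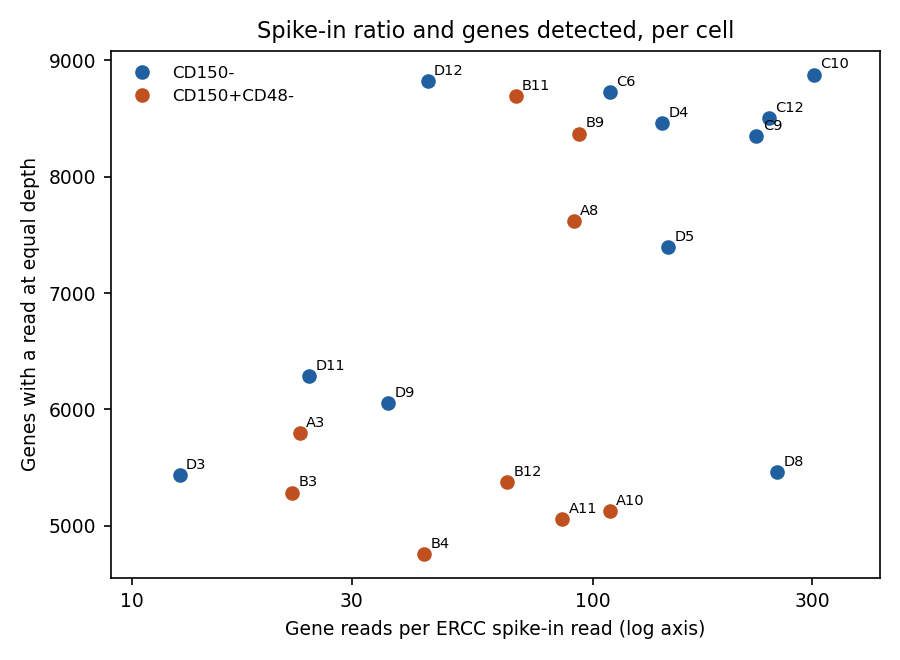
Gene reads per ERCC spike-in read (horizontal, log axis) and number of genes with a read after thinning every cell to 660007 gene reads (vertical), 1 point per cell with its title code. The medians were 68.1 and 5374 for the 9 CD150+CD48- cells and 141 and 8350 for the 11 CD150- cells, with overlapping ranges.

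Members of the HSC list had reads in a share of cells that was on average 36.5 percentage points higher in CD150+CD48- cells, against -8.95 in random lists. Tek, a receptor of angiopoietins, was 39.2-fold higher (95% CI 21.7 to 79.3), in 5 of 9 and 1 of 11 cells, with a log2 fold of 3.13 without B4 and 5.92 without D9 in place of 4.59. Cdkn1c (chromosome 7, 143458339 to 143461050), which encodes the cell cycle inhibitor p57, had 40.9 CPM (95% CI 35.9 to 46.4) in 4 of 9 cells and no read in CD150- cells, at least 99.0-fold higher. Hlf, a transcription factor of stem cells, was read in 7 of 9 and 5 of 11 cells but had 453 CPM (95% CI 436 to 470) against 654 (95% CI 635 to 673). Of its 4746 thinned reads in CD150- cells 2363 were in D3, and without D3 its log2 fold was 0.33 in place of -0.53. Robo4 had 7.58 against 8.54 CPM, and all its reads in CD150- cells were in D9. Its log2 fold was 3.10 without D9 and -1.54 without A3. With 0 reads at the floor the list's median was 1.63.

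In the megakaryocyte and platelet list, members were read in a share of cells 33.5 percentage points higher on average. Rab27b (chromosome 18, 69979131 to 70141605), which acts in platelet granule secretion, had 96.0 CPM in 6 of 9 cells and no read in CD150- cells, at least 232-fold higher. Of its 570 thinned reads 378 were in A10, without which its log2 fold was 5.22 in place of 6.60. Itgb3, the beta chain of the platelet fibrinogen receptor, was at least 205-fold higher but was read in 3 of 9 cells, with 401 of 503 reads in A8 and a log2 fold of 4.34 without A8 in place of 6.42. Itga2b, its partner chain, was 37.6-fold higher (95% CI 26.0 to 56.4), and Vwf, von Willebrand factor, 4.35-fold (95% CI 3.82 to 4.97). The log2 fold of Itga2b was 3.87 without A8 and 5.91 without C6 in place of 4.92, and that of Vwf 4.53 without D8 in place of 2.09. Gp1ba had 7.58 CPM in 3 of 11 CD150- cells and no read in CD150+CD48- cells, at least 15.0-fold lower, with a log2 fold of -2.26 without D4 in place of -3.10. Gp5 was 3.48-fold lower (95% CI 1.13 to 14.2), with a log2 fold of 0.20 without C10 and -1.74 without A8. The list took 0.489% of gene reads in A8 and 0.405% in B4, and 0.0311% to 0.168% in the other 7 CD150+CD48- cells. In D3, D9, D11 and D12 it took 0.0227% to 0.151%, and in the other 7 CD150- cells 0.00288% to 0.0456%. Its median was 3.93 with 0 reads at the floor, 4.00 without D11, 3.62 without C10 and 3.54 without D8 or without D9.

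Erythroid members had reads in a share of cells that was -50.7 percentage points apart on average, against -9.20 in random lists. Car1 (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368), carbonic anhydrase 1, had 4724 CPM (95% CI 4674 to 4774) in CD150- cells and 0.505 CPM (3 reads) in CD150+CD48- cells, 9354-fold lower (95% CI 3200 to 45358). Ermap, an erythroid membrane protein, had 436 CPM against 0.168 (1 read), 2591-fold lower (95% CI 465 to 102378). Klf1 and Gata1, transcription factors of the erythroid lineage, were 10.5-fold (95% CI 9.07 to 12.1) and 10.6-fold (95% CI 8.74 to 13.0) lower. All 202 thinned reads of Klf1 in CD150+CD48- cells were in B4, without which its log2 fold was -8.48 in place of -3.35. That of Gata1 was -4.79 without B3 in place of -3.34, and that of Car1 -12.21 without B4 in place of -11.62. Car2 and Gfi1b differed least, at 3.13-fold (95% CI 3.03 to 3.23) and 2.57-fold (95% CI 2.32 to 2.85) lower, and in cells of letters B and D alone Gfi1b had a log2 fold of 0.02, against -2.35 without B12 and -1.35 with all cells. Haemoglobin genes have near-identical copies and their levels are uncertain. The list's median was -5.54 with 0 reads at the floor, -5.47 without B4, -5.39 without B11 and -5.33 without A8.

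Members of the G2/M list were read in a share of cells -53.9 percentage points apart on average, against -11.8 in random lists. Ccna2, cyclin A2, had 460 CPM (95% CI 444 to 476) in 10 of 11 CD150- cells and 0.505 CPM (3 reads) in CD150+CD48- cells, 911-fold lower (95% CI 311 to 4418). Ccnb2, cyclin B2, had 214 CPM in 8 of 11 cells and no read in CD150+CD48- cells, at least 424-fold lower. Ckap2 was 2.27-fold lower (95% CI 1.65 to 3.16), but 53 of its 54 thinned reads in CD150+CD48- cells were in B9, and its log2 fold was -4.19 without B9 in place of -1.10. Cenpe, a kinetochore motor, had 46.0 against 37.1 CPM, but was read in 2 of 9 and 7 of 11 cells, and its log2 fold was -3.24 without B4 and 1.05 without D5. The list's median was -4.85 with 0 reads at the floor, -5.62 without B9, -5.59 without B4 and -5.45 without B11.

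Of the 25 S phase genes, 20 were lower in CD150+CD48- cells, with a median log2 fold of -0.84 (percentile 0.205) and a share difference of -24.8 percentage points. The difference went with the 7 CD150- cells rich in erythroid reads, in which the list took 0.940% to 1.66% of gene reads. D3, D9, D11 and D12 had 0.107% to 0.176%, below the CD150+CD48- median of 0.388% (range 0.0360 to 1.46). Ccne1, cyclin E1, had 420 CPM against 0.168 (1 read), 2492-fold lower (95% CI 447 to 98468), and Rrm2, a subunit of ribonucleotide reductase, was at least 346-fold lower. Chaf1b, of the chromatin assembly factor, was 2.07-fold higher (95% CI 1.88 to 2.28) and Ung, uracil-DNA glycosylase, 2.70-fold (95% CI 1.86 to 3.97). The direction of both turned in cells of letters A and C, at log2 folds of -0.02 and -1.65, and that of Ung without B4, at -1.26 (2.38 without D5). The list's median was -1.54 without B9, and in cells of letters B and D it did not stand apart, at -0.10 (percentile 43.4). The G1 cyclins and CDK inhibitors did not stand apart, with a median of 0.20 (percentile 73.4), a share difference of 1.55 percentage points and 10 of 13 members higher. In it Ccnd2, cyclin D2, was 15.4-fold higher (95% CI 13.2 to 18.0), in 9 of 9 and 4 of 11 cells, Cdkn2c was 13.0-fold lower (95% CI 8.83 to 20.0) and Cdk4 1.56-fold lower (95% CI 1.50 to 1.63). Ccnd2 was at a log2 fold of 5.87 without D12 in place of 3.89, and Cdkn2c at -5.45 without B9 in place of -3.44.

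Cells of the CD150- group differed widely in these lists. The erythroid list took over 0.5% of gene reads in 7 of 11 CD150- cells (63.6%, 95% CI 30.8 to 89.1), from 0.995% in D4 to 2.37% in C9, and in none of the 9 CD150+CD48- cells, which allows a share of up to 33.6%. It took 0.0946% in D11, 0.0189% in D12, 0.249% in D3 and 0.122% in D9, and 0.0156% to 0.306% in CD150+CD48- cells. The HSC list took 0.626% in D11, 0.804% in D12, 1.03% in D3 and 0.898% in D9, and 0.0132% to 0.0580% in the other 7 CD150- cells. In CD150+CD48- cells it took 0.349% to 1.35%. The G2/M list took 0.000817% in D11, 0.0319% in D12, 0.0333% in D3 and 0.00229% in D9, and 0.410% to 0.876% in the other 7 CD150- cells, against 0.00121% to 0.168% in CD150+CD48- cells.

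**Figure D2:**
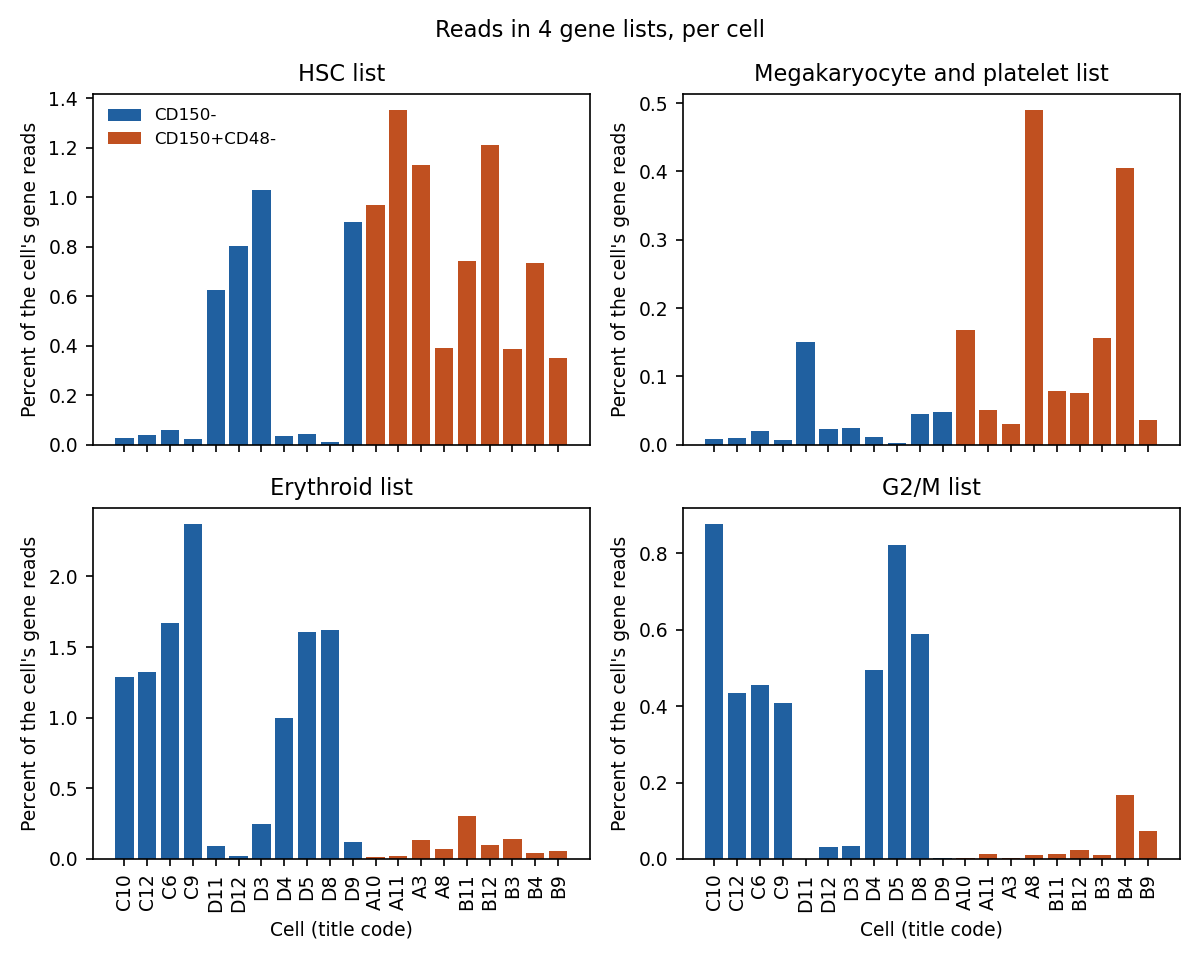
Percent of each cell's gene reads in the HSC, megakaryocyte and platelet, erythroid and G2/M lists (vertical), 1 bar per cell by title code, blue for CD150- and orange for CD150+CD48- cells. The erythroid list reached 2.37% in C9 and was 0.0189% in D12, both CD150- cells, and was at most 0.306% in a CD150+CD48- cell.

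Among lists of other lineages, 5 of 7 neutrophil and monocyte genes were higher in CD150+CD48- cells, with a median log2 fold of 1.31 (percentile 98.5) and a share difference of 17.5 percentage points. The list took 0.0158% to 0.0772% of gene reads in the 7 CD150- cells rich in erythroid reads and 0.0667% to 0.102% in the other 4, the latter within the CD150+CD48- range of 0.0262% to 0.149%. Lyz2, lysozyme, was 4.33-fold higher (95% CI 3.83 to 4.91), in 9 of 9 and 4 of 11 cells, and Nkg7, a granule protein, 11.8-fold (95% CI 8.37 to 17.0), in 2 of 9 and 1 of 11. Calr, a chaperone of the endoplasmic reticulum, was 2.86-fold lower (95% CI 2.64 to 3.10) and Ctss, a cathepsin, 15.1-fold lower (2 reads, 95% CI 3.90 to 130). Lyz2 had 827 of its 1184 thinned reads in CD150+CD48- cells in B4, and its log2 fold was 0.55 without B4 and 2.86 without D11 in place of 2.09. Nkg7 had 268 of 356 in A8 and was at 1.53 without A8 and 5.93 without D11 in place of 3.32, and Ctss was at -1.08 without D9 in place of -2.19. This list did not stand apart when any of 6 cells (C10, C12, D4, D12, A3 and B3) was left out, and was lowest at 0.87 without B3. It did not stand apart with no gene filter (0.22), with a filter of 50 reads and 5 cells (percentile 97.3) or in cells of letters B and D (0.26). Lymphoid-primed genes had a median of -0.01 (percentile 52.0), with 3 of 7 members higher, and a share difference of 19.5 percentage points (percentile 99.9), and without D11 their median was 1.43 (percentile 97.1). Of gene reads they took 0% to 0.00214% in the 7 CD150- cells rich in erythroid reads and 0.0269% to 0.238% in the other 4. CD150+CD48- cells had 0.0256% to 0.223%. Il12a was 4.65-fold (95% CI 4.10 to 5.28) and Cd27 3.96-fold (95% CI 3.31 to 4.77) higher, each in 7 of 9 and 3 of 11 cells. Il12a was at a log2 fold of 4.29 without D9 in place of 2.19, and Cd27 at 1.33 without B3 and 2.63 without D12 in place of 1.94. Satb1 was 9.89-fold lower (95% CI 6.51 to 15.7) but had a log2 fold of 3.22 in cells of letters A and C, and -4.89 without A3 and -2.30 without D3 in place of -3.02. Flt3 had 46.3 against 52.8 CPM, most of the latter in D11, with a log2 fold of 2.81 without D11 and -1.77 without A3.

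Of the 11 genes of MHC class I presentation, 9 were higher in CD150+CD48- cells, with a median log2 fold of 1.08 (percentile 99.7) and a share difference of 15.7 percentage points. The list took 0.168% to 0.704% of gene reads in the 7 CD150- cells rich in erythroid reads and 0.516% to 1.58% in the other 4, against 0.550% to 2.70% in CD150+CD48- cells, so the difference went largely with the 7 cells. H2-T23, a non-classical class I gene, was 5.01-fold higher (95% CI 4.70 to 5.34) with reads in all 20 cells, and Tap2, a subunit of the peptide transporter, 17.2-fold (95% CI 11.6 to 26.4), with a log2 fold for Tap2 of 2.75 without A8 and 5.21 without D12 in place of 3.78. Tapbp was 2.24-fold lower (95% CI 1.55 to 3.28), and Psmb9 had 78.6 against 83.7 CPM, with a log2 fold of 1.38 without D12. Class I genes have close paralogs and may share reads with them, which was not measured, so their levels are uncertain. The median was 2.00 without D12, and in cells of letters B and D the list did not stand apart, at 0.53 (percentile 92.5).

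Of 74 nuclear genes of oxidative phosphorylation, 63 were lower in CD150+CD48- cells, with a median log2 fold of -0.53 (percentile 0.22). Their share difference of -8.29 percentage points was near the -9.90 of random lists (percentile 72.4). The list took 1.60% to 2.58% of gene reads in the 7 CD150- cells rich in erythroid reads. In the other 4 it took 0.485% to 0.928%, below the CD150+CD48- median of 1.05%, so the difference went with the 7 cells. Ndufa9 and Ndufc2, subunits of complex I, were 24.6-fold (95% CI 18.4 to 33.5) and 4.22-fold (95% CI 3.17 to 5.69) lower, and without B9 the log2 fold of Ndufa9 was -6.99 in place of -4.46. Ndufv3 was 1.97-fold higher (95% CI 1.68 to 2.31) and Cox7a2l 1.79-fold (95% CI 1.70 to 1.88), the latter with log2 folds of -0.40 for the mean on the log scale and -0.41 in cells of letters B and D. The list did not stand apart with the mean on the log scale (-0.79, percentile 26.6) or in cells of letters B and D (-0.14, percentile 40.1). Of 15 glycolysis genes, 9 were higher, with a median of 0.70 (percentile 97.6) and a share difference of 3.43 percentage points. Both kinds of CD150- cells had lower median shares of this list, 0.220% and 0.213% against 0.377%. The ranges overlapped, at 0.181% to 0.260% in the 7 cells rich in erythroid reads, 0.143% to 0.296% in the other 4 and 0.249% to 0.459% in CD150+CD48- cells. Hk2, hexokinase 2, had 31.1 CPM in 4 of 9 cells and no read in CD150- cells, at least 75.4-fold higher, while the phosphofructokinases Pfkl and Pfkm were 10.4-fold (95% CI 6.96 to 16.1) and 2.44-fold (95% CI 2.10 to 2.84) lower. Hk2 was at a log2 fold of 4.14 without A3 in place of 5.01, and Pfkl at -4.10 without B9 in place of -3.11. Gapdh, which has many pseudogenes, had an uncertain 16.8 against 1.52 CPM, and a log2 fold of -0.68 without B3. The glycolysis list did not stand apart when any of 14 cells was left out, and its median was 0.047 without B3. Nor did it with unthinned reads (0.32), with a filter of 50 reads and 5 cells (0.37) or in cells of letters A and C (0.31) or B and D (0.29).

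**Figure D3:**
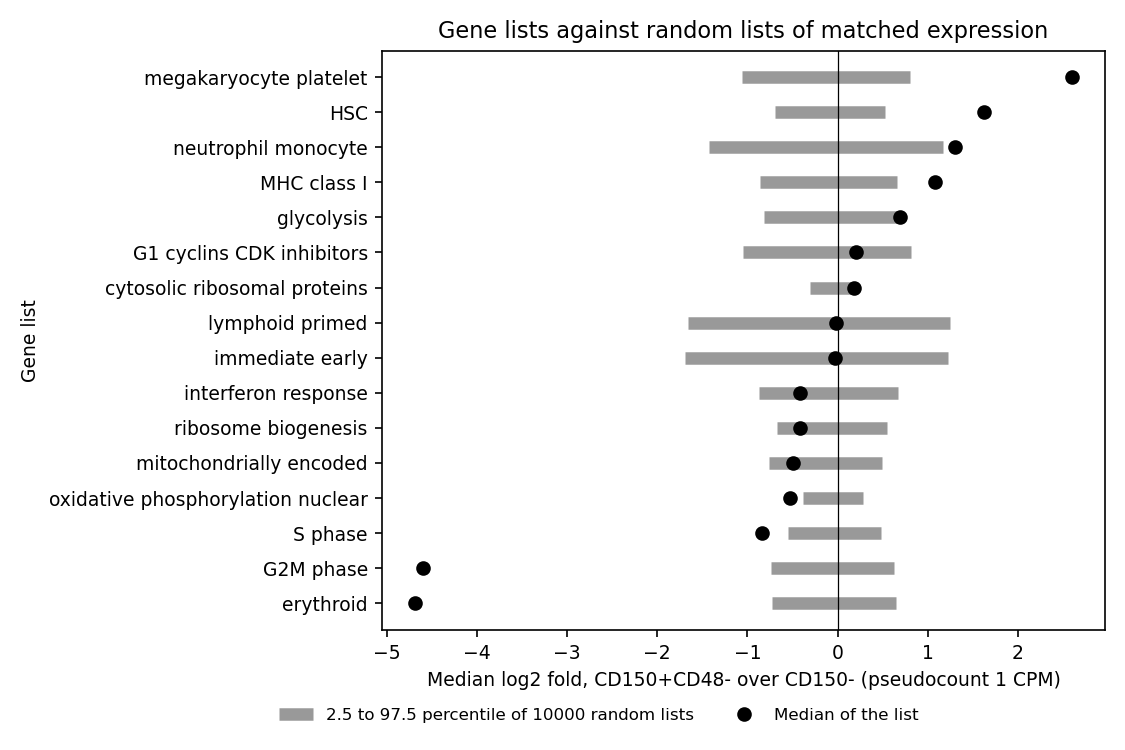
Median log2 fold of each of 16 gene lists, CD150+CD48- over CD150- (points, pseudocount of 1 CPM), with the range of the middle 95% of 10000 random lists of matched expression (grey bars). The megakaryocyte and platelet list was highest at 2.60 and the erythroid list lowest at -4.68.

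The other lists did not stand apart. Ribosome biogenesis genes had a median log2 fold of -0.42 (percentile 11.3), with 13 of 20 lower and a share difference of -17.0 percentage points. Dkc1 and Pes1 were 5.80-fold (95% CI 5.12 to 6.58) and 5.47-fold (95% CI 4.49 to 6.73) lower, Wdr43 was 2.07-fold higher (95% CI 1.92 to 2.24) and Myc 1.72-fold higher (95% CI 1.57 to 1.89), with a log2 fold for Myc of -0.25 without A3 and for Dkc1 of -3.73 without B9 in place of -2.51. Cytosolic ribosomal protein genes had a median of 0.18 (percentile 94.9) and a share difference of -1.20 percentage points, with 57 of 86 higher. Rpl15 was 2.84-fold higher (95% CI 2.64 to 3.07) and Rpl5 2.65-fold (95% CI 2.24 to 3.15), but without B3, which had 283 of the 438 thinned reads of Rpl5 in CD150+CD48- cells, its log2 fold was 0.07 in place of 1.37, and in cells of letters A and C it was -2.21. Rpl15 was at 0.84 without B12 in place of 1.50. Rpl39l was at least 24.0-fold lower and Rpl10 3.03-fold (95% CI 2.48 to 3.72), with a log2 fold for Rpl39l of -1.64 without C9 in place of -3.71. Mitochondrially encoded genes had a median of -0.50 (percentile 10.4) and a share difference of -4.62 percentage points, with 11 of 14 lower. Of these mt-Nd2 was 2.14-fold lower (95% CI 2.05 to 2.23) and mt-Nd3 2.93-fold (95% CI 1.52 to 6.11), while mt-Co2 and mt-Atp6 had 11 and 10 reads against 9 and 10.

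Immediate early genes had a median log2 fold of -0.03 (percentile 54.6), with 4 of 9 members higher and a share difference of -3.48 percentage points. Their median was -1.20 without B9, 0.70 without D12 and 0.60 without C12. Ier3 was 27.1-fold higher (95% CI 17.5 to 44.2) and Klf2 166-fold (1 read in CD150- cells, 95% CI 29.3 to 6613), while Dusp1 was 19.4-fold lower (95% CI 12.1 to 33.1) and Junb at least 9.55-fold lower. Leaving out 1 cell moved the log2 fold of Ier3 from 4.35 to 3.03 (B3) or 4.98 (D12), of Klf2 from 4.39 to 3.49 (B11) and of Dusp1 from -3.89 to -5.90 (B9) or -2.40 (D12). Interferon response genes had a median of -0.42 (percentile 17.9), with 7 of 16 higher and a share difference of -4.36 percentage points. The median log2 fold of this list was 1.12 (percentile 99.7) without D12 and 0.39 without D11. Its share of gene reads was 0.0301% to 0.0819% in the 7 CD150- cells rich in erythroid reads and 0.121% to 0.852% in the other 4. In CD150+CD48- cells it was 0.108% to 0.582%, above all 7. The median share was 0.247% in CD150+CD48- and 0.0662% in CD150- cells, opposite in direction to the median log2 fold. Ifitm1 was 4.89-fold higher (95% CI 4.63 to 5.17), in 8 of 9 and 4 of 11 cells, and Rsad2 6.33-fold (95% CI 4.80 to 8.47). The log2 fold of Rsad2 was 5.76 without C10 and 1.58 without B12 in place of 2.53, that of Ifitm1 1.65 without A3 and 2.90 without D12 in place of 2.28, and that of Isg15 -2.94 without D12 in place of -3.62. Isg15 was at least 22.4-fold lower, and Ifit1 22.7-fold lower (95% CI 12.1 to 47.8) with 273 of its 277 thinned reads in CD150- cells in D11. The log2 fold of Ifit1 was 0.74 without D11 and -5.29 without B11.

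By the share of cells with a read, the 12 genes that differed most toward CD150+CD48- cells were Mtss1l, Nrgn, Ppp1r9a, Cd9, Trpc6, Tbc1d16, Dock1, Cul9, As3mt, Tie1, Ctla2a and Rbpms. Mtss1l (chromosome 8, 110721476 to 110741400) was read in 9 of 9 CD150+CD48- cells and no CD150- cell, at 15.0 CPM (95% CI 12.0 to 18.4), at least 36.3-fold higher. Dock1 (chromosome 7, 134670654 to 135173639), an activator of the GTPase Rac, was read in 7 of 9 cells at 112 CPM (95% CI 104 to 121) and in no CD150- cell, at least 272-fold higher. Tbc1d16 and Cul9 were likewise read in 7 of 9 and no CD150- cell, at least 341-fold and 149-fold higher. Cd9 (chromosome 6, 125460266 to 125494791), a tetraspanin, was 116-fold higher (95% CI 53.1 to 318), in 8 of 9 and 1 of 11 cells. Tie1, a receptor related to Tek, was 11.8-fold higher (95% CI 9.74 to 14.3), Trpc6, a cation channel, 14.4-fold (95% CI 12.1 to 17.2) and As3mt 14.3-fold (95% CI 12.4 to 16.7). Ctla2a, Rbpms, Nrgn and Ppp1r9a were 5.72-fold, 5.50-fold, 4.48-fold and 3.14-fold higher, each in 9 of 9 cells. Single cells moved several log2 folds. Without D3, Tie1 was at 5.30 in place of 3.48, Nrgn at 3.48 in place of 2.14, Rbpms at 3.33 in place of 2.43 and Ppp1r9a at 2.98 in place of 1.60. Without D11, As3mt was at 6.82 in place of 3.79 and Ctla2a at 3.97 in place of 2.51. Trpc6 was at 8.13 without D12 in place of 3.78, Cd9 at 6.60 without D12 and 4.64 without B4 in place of 5.73. Without A10 Tbc1d16 was at 5.86 in place of 7.15, without B3 Cul9 at 5.20 in place of 5.96, and without B4 Ppp1r9a at 0.93.

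Toward CD150- cells the 12 genes were Ect2, Usp34, Timm13, Mrps36-ps1, Acss1, Clybl, Ap1ar, Aar2, Polq, Ints13, Irf7 and Rnf121. Ect2 (chromosome 3, 27097222 to 27153878), which is needed for cytokinesis, was read in 9 of 11 CD150- cells at 88.7 CPM (95% CI 82.0 to 95.8) and in no CD150+CD48- cell, at least 176-fold higher in CD150- cells. Usp34, a deubiquitinase, and Timm13, of the mitochondrial import machinery, were read in 9 of 11 CD150- cells and no CD150+CD48- cell, at least 104-fold and 44.7-fold higher in CD150- cells. Acss1 (chromosome 2, 150618105 to 150668500), a mitochondrial acetyl-CoA synthetase, was 337-fold higher in CD150- cells (95% CI 131 to 1237), in 10 of 11 and 1 of 9 cells. Polq, DNA polymerase theta, was 13.0-fold higher in CD150- cells (95% CI 10.1 to 17.0) and Irf7, a transcription factor of interferon signalling, 12.3-fold (95% CI 8.68 to 18.1). Clybl, Ap1ar and Ints13 were 60.5-fold, 34.7-fold and 14.7-fold higher there, and Aar2 and Rnf121, with 1 read each in CD150+CD48- cells, 134-fold (95% CI 23.7 to 5332) and 63.0-fold (95% CI 11.0 to 2520). Mrps36-ps1 is a processed pseudogene with 13 reads and is uncertain. The thinned reads of Polq and Ap1ar in CD150+CD48- cells came from B9, without which their log2 folds were -7.14 in place of -3.58 and -6.81 in place of -4.74. Without B11, Irf7 was at -6.12 in place of -3.41 and Clybl at -6.18 in place of -5.05. Without A8, Ints13 was at -5.43 in place of -3.48 and Acss1 at -7.83 in place of -7.09, and without D9 Ap1ar was at -3.84.

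Cells of 1 group also differed by title letter, which gives a scale for the differences between groups. For each list the larger in size of 2 median log2 folds, B over A and D over C, was set against that between the groups. In 13 of the 16 lists it was larger, and the exceptions were the erythroid, megakaryocyte and platelet, and glycolysis lists. The larger of 2 values, each from fewer cells and from the members past the filter in them, tends to be large. It readily exceeds a group median near 0. The HSC list had 4.91 for letter D over C and -0.64 for B over A. For D over C it was 6.05 in the lymphoid-primed, 3.42 in the neutrophil and monocyte, 1.86 in the interferon, 1.45 in the MHC class I and -0.70 in the oxidative phosphorylation list. For B over A it was 1.06 in the S phase list and, over 4 members, 4.86 in the G2/M list. The erythroid list had -0.56 for D over C and, over 4 of its members, 0.97 for B over A, and the megakaryocyte and platelet list 0.10 and -0.27. All 4 cells of letter C were rich in erythroid reads, and D3, D9, D11 and D12 were not, so D over C also compares kinds of cells.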

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

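The measures compared in this part were listed after the values per cell had been seen. For the 9 CD150+CD48- cells, 20 measures per cell were compared with Dixon's 95% critical value for the gap between the farthest cell and its neighbour over the whole range, and 3 exceeded it. About 1 in 20 would do so by chance if the values were independent and normally distributed. That was not checked, and many of the measures are shares near 0. The 11 CD150- cells were not tested in this way. The erythroid list took 0.306% of gene reads in B11, against 0.139% in the next cell, a gap of 0.574 of the range. The lymphoid-primed list took 0.223% in B3, against 0.0782% in the next cell, a gap of 0.734. The G2/M list took 0.168% in B4, against 0.0731% in the next cell, a gap of 0.5684.

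Among CD150- cells the erythroid list took over 0.5% of gene reads in 7 of 11, while D3, D9, D11 and D12 had HSC list shares in the range of CD150+CD48- cells. All tests of this pattern were chosen only after the result was seen. Carry-over of erythroid RNA into wells of HSC-like cells would leave their HSC reads in place. Yet 0 of the CD150- cells over 0.5% had an HSC list share at or above that of the lowest CD150+CD48- cell. Added RNA also lowers this share, and the 7 cells had 109 to 302 gene reads per ERCC read, against 12.7 to 43.8 in D3, D9, D11 and D12. The count therefore speaks only against carry-over too small to dilute the HSC share, and heavy carry-over is left open. D3, D9, D11 or D12 exchanged with a cell of the erythroid kind would leave that partner among the CD150+CD48- cells, whose highest erythroid share was 0.306%. Slamf1 reads in 0 of the CD150- cells and HSC list shares of at least 0.349% in all 9 CD150+CD48- cells go with the labels as given, but a wrong label on single cells without such a partner, or an exchange of all labels between the groups, cannot be told apart from a true sort, since Slamf1 was read in only 3 of the 9 CD150+CD48- cells. It stays an open hypothesis that the CD150- gate, which names no CD48, may hold progenitors of several kinds, and no biological explanation was tested.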

How the results depend on the processing

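Of the alternatives tried, the floor of 3 reads without a pseudocount and leaving out the cells with over 40% of reads unaligned (A10, A11 and B4) were chosen after seeing the data. The HSC, megakaryocyte, erythroid and G2/M lists kept their direction and stood apart under every alternative with random lists, over ranges of the median log2 fold from 0.91 to 5.56, 2.16 to 4.52, -7.12 to -3.10 and -7.35 to -2.76. TMM, median-of-ratios and spike-in factors multiply all genes of a group alike, so a list and its random lists shift together. Whether a list stands apart could hardly change with these factors, so they are no test of it. The 24 genes chosen by share of cells kept the sign of their log2 fold under every alternative, which for leaving out single cells follows from how they were chosen. The mean on the log scale and scaling to the spike-ins moved the median of all genes by -0.40, and letters A and C alone by -0.25. TMM and median-of-ratios factors moved it by 0.04, and with these, the mean of each cell's CPM, unthinned reads or another seed no list median moved by more than the spread of random lists. No gene took over 5% of a cell's reads, no cell had under 0.5 times the median number of genes, and the series table equalled the cells' files, so these 3 alternatives could not give other values. Values below are median log2 folds, or share differences (CD150+CD48- minus CD150-) in percentage points, and the cause was not tested unless stated. Depth limits the detection of single genes: 1 read in a thinned cell was 1.52 CPM.

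With the mean on the log scale medians were 2.72 for HSC, -4.06 erythroid, -1.95 S phase, -3.91 G2/M, -1.33 ribosome biogenesis, -0.79 oxidative phosphorylation (no longer apart) and 2.05 MHC class I, and ribosomal proteins stood apart (0.10). Spike-in scaling multiplied all CD150+CD48- levels by 1 factor, from the summed reads of each group, before the pseudocount was added. D3, D9, D11 and D12 had 70256 to 197763 ERCC reads, against at most 40132 in any other CD150- cell. They therefore weighed most in the CD150- sum of ERCC reads. With spike-in scaling medians were 1.16 HSC, -1.30 S phase, -0.88 ribosome biogenesis, -0.29 cytosolic ribosomal proteins, -0.99 oxidative phosphorylation and -0.96 mitochondrially encoded. They were 0.24 for glycolysis, -0.87 interferon and 0.61 MHC class I. A pseudocount of 0.1 CPM gave 3.90 for the megakaryocyte and -7.12 for the erythroid list, and 10 CPM gave -3.10 erythroid and -2.76 G2/M, which follows from the pseudocount's weight on low levels. With 3 reads in place of 0 and no pseudocount the megakaryocyte list was at 3.93 and the erythroid list at -5.54.

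With no gene filter the megakaryocyte list was at 3.13, erythroid at -4.13 and neutrophil and monocyte at 0.22 (no longer apart). With at least 50 reads and 5 cells the megakaryocyte list was at 3.77 with a share difference of 46.5, the interferon list at 0.29, and the neutrophil and glycolysis lists no longer stood apart, the latter at 0.37. At least 5 thinned reads for a cell to count gave share differences of 24.9 for the megakaryocyte and -12.3 for the oxidative phosphorylation list, and a median of 5686 genes in CD150- cells. A depth of 0.5 of the main one gave 3.09 for the megakaryocyte list. Unthinned reads ended the call of the glycolysis list (0.32) and put the ribosomal proteins apart (0.19).

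All cells of letter C, but of letter D only D4, D5 and D8, were rich in erythroid reads. Subsets by letter therefore also differ in their mix of kinds of CD150- cells. In cells of letters A and C medians were 5.56 HSC, 4.52 megakaryocyte, -6.20 erythroid, 3.83 neutrophil and monocyte, 6.88 lymphoid-primed, -2.02 S phase, -7.35 G2/M and -1.23 ribosome biogenesis. They were -0.11 for cytosolic ribosomal proteins, -1.29 oxidative phosphorylation, 0.31 glycolysis (no longer apart), -1.81 immediate early, 0.79 interferon and 2.01 MHC class I. Lymphoid-primed and ribosome biogenesis lists stood apart there. Share differences were 56.9 HSC, -83.3 erythroid, 40 neutrophil and monocyte, 56.2 lymphoid-primed, -52.0 S phase, -92.0 G2/M, -12.5 G1, -35.0 ribosome biogenesis, -16.1 oxidative phosphorylation, -12.5 mitochondrially encoded and -50.0 immediate early. In cells of letters B and D medians were 0.91 HSC, 3.31 megakaryocyte, -2.88 G2/M, 0.73 G1 and -1.09 interferon (apart). No longer apart were neutrophil and monocyte at 0.26, S phase at -0.10, oxidative phosphorylation at -0.14, glycolysis at 0.29 and MHC class I at 0.53, while ribosomal proteins stood apart at 0.30. Share differences were 28.2 HSC, 52.2 megakaryocyte, -30.9 erythroid, 8.98 lymphoid-primed, -7.89 S phase, -30.1 G2/M, 8.81 G1, -5.29 ribosome biogenesis, -3.36 oxidative phosphorylation and 5.31 immediate early.

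Without the 3 cells with over 40% unaligned reads the erythroid list was at -5.44 and G2/M at -5.59, with share differences of -10.1 for ribosome biogenesis, -5.06 oxidative phosphorylation and 10.1 glycolysis. The glycolysis list no longer stood apart (0.49) and ribosomal proteins did (0.27).

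Leaving out each cell in turn gave, from lowest to highest, medians of 1.31 to 2.11 for HSC, 2.16 to 4.00 megakaryocyte, -5.47 to -4.22 erythroid, -0.14 to 1.43 lymphoid-primed, -1.54 to -0.67 S phase, -5.62 to -4.02 G2/M, 0.047 to 0.79 glycolysis, -1.20 to 0.70 immediate early, -0.80 to 1.12 interferon and 0.82 to 2.00 MHC class I. Share differences ran over 31.2 to 42.0 for megakaryocyte, -56.8 to -47.9 erythroid, 15.7 to 29.8 lymphoid-primed, -30.2 to -20.2 S phase and -59.9 to -51.1 G2/M. The calls of the glycolysis and the neutrophil and monocyte lists ended when any of 14 and of 6 cells was left out. The interferon list stood apart without D12, and ribosomal proteins without C10, B12 or B4. The list calls not named here were kept.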

Other observations

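Of the tests in this part, those of depth and of mRNA per cell were chosen only after the result was seen, and the test of reads shared with nuclear copies was not. Il1rl1, the receptor of interleukin 33, was the member of the mast cell, basophil and eosinophil list that passed the filter. It was read in 7 of 11 CD150- cells at 45.9 CPM (95% CI 41.1 to 51.1) and in no CD150+CD48- cell, at least 90.8-fold higher in CD150- cells. The 7 cells, C6, C9, C10, C12, D4, D5 and D8, were those in which the erythroid list took over 0.5% of gene reads. Lymphoid-primed reads took 0.238% in D11 and 0.157% in D9, against 0.0269% in D12 and 0.0420% in D3, and Dntt, a marker of early lymphoid cells, was read in D11 alone, with 6 reads.

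Markers of mature cells were read in cells of both groups. Cd79b, a part of the B cell receptor and the member of the mature B list past the filter, was 5.69-fold higher in CD150+CD48- cells (95% CI 4.69 to 6.96), in 6 of 9 and 2 of 11 cells, with 1333 reads in B3 and a log2 fold of 0.80 without B3 and 6.26 without C9 in place of 2.44. Lck, the member of the mature T and NK list past the filter, was 1.94-fold lower (95% CI 1.42 to 2.68), in 3 of 9 and 1 of 11 cells, with all reads of CD150- cells in D11 and a log2 fold of 3.45 without D11 in place of -0.89. Cd163, from the macrophage list, was 1.64-fold lower (95% CI 1.08 to 2.51), in 2 of 9 and 3 of 11 cells and at a log2 fold of -1.51 without A8 in place of -0.63, and Vcam1 of the same list had 745 reads in D12. No member of the mature neutrophil or of the stroma and endothelium list passed the filter. Of the former, Lcn2, S100a8 and S100a9 had 462, 346 and 183 reads in A3. Of the latter, Col1a2 had 260 reads in B4 and 241 in B11. Cpa3, a mast cell protease, had 135 reads in B3 and none in the other 19 cells. In D12 the interferon list took 0.852% and the immediate early list 0.147% of gene reads, the highest of all cells in both.

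Fewer genes were detected in CD150+CD48- cells by the group medians. Sequencing depth as the whole reason is argued against, since after thinning to equal depth the ratio of the group medians was 0.644. Less mRNA per cell remains open: the medians of gene reads per spike-in read had a ratio of 0.481, but D3, D9, D11 and D12, with a median of 30.2 against 68.1 in CD150+CD48- cells, had a median of 6168.5 genes against 5374. Between cells above and below the median of gene reads per spike-in read the numbers of genes overlapped, at 5057 to 8370 against 4758 to 5798 in CD150+CD48- cells and 5461 to 8877 against 7393 to 8729 in CD150- cells rich in erythroid reads. A difference between the letters in handling cannot be told apart from the sort, and no biological explanation was tested.

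Of 13 mitochondrially encoded mRNAs, 6 were under 20 CPM in both groups while 7 were over 100 CPM. Reads shared with nuclear copies could leave the former uncounted, and a median of 99.2% of their 50-base windows was found in another gene, against 7.61% for the latter. This cannot be told apart from other reasons for low counts. Windows were sought in annotated transcripts of GENCODE M21 only, so copies elsewhere in the genome would be missed. mt-Atp8 was low with 0% of its windows shared, which therefore does not show that it has no copy. mt-Nd4 and mt-Co1 were over 1000 CPM with 62.2% and 51.1% shared, and reads from the rest of their windows could still be counted. No biological explanation was tested.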
